A study of Arabidopsis thaliana with 12 samples.

How the data were processed

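Ribosome-protected fragments (RPF) and total RNA were sequenced from whole rosettes of Arabidopsis thaliana Col-0. Per the labels, plants aged 3 weeks were kept at 8 µmol photons m-2 s-1 (low light, LL) for 10 days and then either stayed there or received 800 µmol photons m-2 s-1 (high light, HL) for 10 min. Per the labels, polysomes were pelleted through a sucrose cushion and digested with RNase If for RPF libraries, and total RNA came from the same kind of extract and was depleted of plant rRNA. The 12 libraries formed 4 groups of 3: RPF LL, RPF HL, total RNA LL and total RNA HL.

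Per the file headers, the deposited values were raw counts per gene from featureCounts 1.5.0-p1, with 1 file per library and no normalization. The headers give a stranded setting of 1 for RPF and 2 for total RNA, alignment with Bowtie2 for RPF and with subjunc for total RNA, and paired reads with chimeric pairs left out. The labels name cutadapt 1.9.1, FastQC 0.11.5, Bowtie2 2.2.9, Subread 1.4.5 and the TAIR10 genome. Each of the 28775 genes was counted over its whole span, introns and untranslated regions included, since length equalled end minus start plus 1 for every gene in the 12 files. All values were whole numbers with different totals per library. Counts per gene and library were not identical between any replicates: over 12 pairs of replicates, chi-square per degree of freedom lay between 7.29 and 59.65.

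Gene names and types came from a RefSeq gene table, which matched 28009 genes by locus tag and 123 of 133 plastid genes by identical coordinates. The 146 mitochondrial genes and 487 nuclear genes had no type there and stayed out of the main tests, which used the 26789 protein-coding genes. Of 26 gene lists written from textbook knowledge, 25 had members in the files, and the mitochondrion-encoded list could not be formed. List members were matched by identifier: 311 had the same name in the reference table, 19 had part of it, 49 had no matching name there, and 79 were listed by identifier alone. No member was left out, and the 49 were kept by their identifiers. The rule fixed beforehand, to drop members whose reference name is that of a different gene, was not applied in the matching. Coordinates are TAIR10 positions from the count files.

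High light was compared with low light separately in RPF and in total RNA with the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), after filterByExpr and TMM normalization. Translational efficiency, meaning RPF relative to total RNA, was tested as the interaction of light and kind of library over all 12 libraries, with TMM factors computed within each kind. Benjamini-Hochberg adjusted p under 0.05 counted as passing, with no minimum fold. Log2 changes are given with their standard error (SE), and CPM are counts scaled to the normalised library size, with the SD over 3 libraries. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, and with fry; adjusted p-values are over the lists of a comparison. At the preset correlation 6 lists passed in RPF, 8 in total RNA and 6 in translational efficiency. With an estimated correlation 0 lists passed in RPF, 0 in total RNA and 0 in translational efficiency. By fry, which asks whether the members move one way on balance, the heat-shock list passed in RPF, and with the block also the Calvin-Benson cycle. Shares of counts were compared with exact two-sided permutation tests that did not use the pairs by number described below. With 3 against 3 these cannot give a p below 0.1. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and DESeq2 1.42.0.

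The labels number the libraries 1 to 3 in each group, and files of the same number share an experiment name, so the numbers were tested as pairs. After removal of group means, LL and HL libraries of the same number correlated across genes at 0.49, 0.45 and 0.30 in RPF and at 0.44, 0.51 and 0.37 in total RNA. The RPF and total RNA libraries of the same number correlated at 0.13 to 0.27, and no correlation between different numbers was above 0.0159. Removing group means lowers correlations between different numbers where those of the same number are positive, so these low values are not separate evidence of pairing. Because libraries of the same number correlated, a fit with the number as a block is given beside the calls over all genes and the list calls that it changes.

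Named genes followed a fixed rule. For each comparison the rule took, from genes past the threshold with a mean log2 CPM of at least 1 and non-overlapping groups, the 10 largest rises and the 10 largest falls, or the 5 smallest p where none passed. In addition it took from each list the 3 members with the smallest p and the most abundant member; genes outside the rule are said to have been chosen after their values were seen. The groups, comparisons, tests, lists, rule for named genes and most alternatives were fixed before the data were examined. Alternatives covered DESeq2 size factors, no filter, a stricter filter of 10 CPM in 3 libraries, DESeq2, limma-voom, all genes instead of protein-coding genes, nuclear genes alone, the block, and leaving out each library in turn. For translational efficiency they also covered TMM over all libraries, a block for each light level and number, and leaving out both libraries of a light level and number. Alternatives chosen after seeing the data were limma-voom and DESeq2 with the block, leaving out the libraries of number 1 with and without the block, and leaving out psbA.

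The tests were tried on simulated data in 3 runs with 200 changed genes each. An unchanged gene had the same mean in low and high light within a number and kind, and the spread came from the fit with the block. Pairing by number was thus built in. The simulations therefore cannot show whether the block suits these libraries, whose same-numbered libraries correlated only in part. At a log2 change of 2 edgeR called 72.0% of changed genes in RPF, 70.1% in total RNA and 27.8% in translational efficiency, and with the block 97.8%, 95.9% and 59.1%. At a log2 change of 1 it called 0%, 1.05% and 0.513%, and with the block 56.6%, 67.9% and 0.513%. Without the block 0 unchanged genes were called; with it 17, 27 and 0 unchanged genes were called in RPF, total RNA and translational efficiency. Total counts ranged from 1563427 to 17312840 in RPF and from 2592499 to 16660558 in total RNA, and counts in protein-coding genes from 1162389 to 2119227 and from 2438332 to 16053563. Intervals from counts cover counting error alone, since reads without molecular identifiers are not independent molecules. Reads that map to near-identical gene copies can be assigned to the wrong copy, so values of CAB1, CAB2, CAB3, LHB1B1 and HSP70 are uncertain as values of single genes.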

Results

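RPF and total RNA were counted per gene in 12 libraries from whole Arabidopsis rosettes, with 3 libraries in each of 4 groups: RPF in low light, RPF in high light, total RNA in low light and total RNA in high light. High light lasted 10 min at 800 µmol photons m-2 s-1, after 10 days at 8 µmol photons m-2 s-1. The RPF libraries of numbers 1, 2 and 3 held 15151983, 1563427 and 2014115 counts in low light and 17312840, 2304228 and 1788894 in high light. The total RNA libraries held 2592499, 10365937 and 8176723 counts in low light and 16660558, 11299241 and 6508222 in high light. Protein-coding genes took 1162389 to 2119227 counts per RPF library and 2438332 to 16053563 per total RNA library. The study concerns how plastids act on cytosolic translation and on nuclear genes while plants acclimate to high light, and the comparisons below ask what changed within the first 10 min.

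The plastid psbA transcript, which encodes the D1 protein of photosystem II, took a larger share of RPF after high light. Its share of protein-coding RPF counts was 10.6% ± 1.71 (SD, n = 3) in low light and 22.9% ± 1.87 (SD, n = 3) in high light, a difference of 12.3 percentage points. In the exact permutation test p was 0.1, the smallest that 3 against 3 allows; this comparison was chosen after the values were seen. In total RNA the psbA share was 42.3% ± 6.67 and 45.6% ± 5.65 (SD, n = 3; exact p = 0.6). All plastid protein-coding genes together took 47.6% ± 4.69 of protein-coding RPF counts in low light and 54.4% ± 3.41 in high light (SD, n = 3; exact p = 0.2), and were higher in high light in 3 of 3 same-numbered pairs, at 42.5%, 51.8% and 48.4% in low light and 51.4%, 58.1% and 53.6% in high light. Their share of total RNA was 65.2% ± 3.59 and 65.7% ± 8.94 (SD, n = 3; exact p = 0.9). Without the most counted gene in each library the high-minus-low difference of the plastid share in RPF was -0.66 percentage points. Across the 14 share tests, which also covered nuclear, mitochondrial, rRNA and tRNA genes, adjusted p ranged from 0.969 to 1. The RPF libraries of number 1 stood apart: nuclear rRNA took 52.1% and plastid rRNA 30.6% of all counts in low light, and 47.5% and 37.2% in high light. In total RNA, low-light library 1 held 3.78% mitochondrial counts against 0.553% to 1.19% in the other libraries. Of all its counts 2.18% came from ATMG00020 and 1.22% from ATMG01390. Mitochondrial genes had no type, so any rRNA among them is in this class and not in the rRNA classes.

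**Figure D1:**
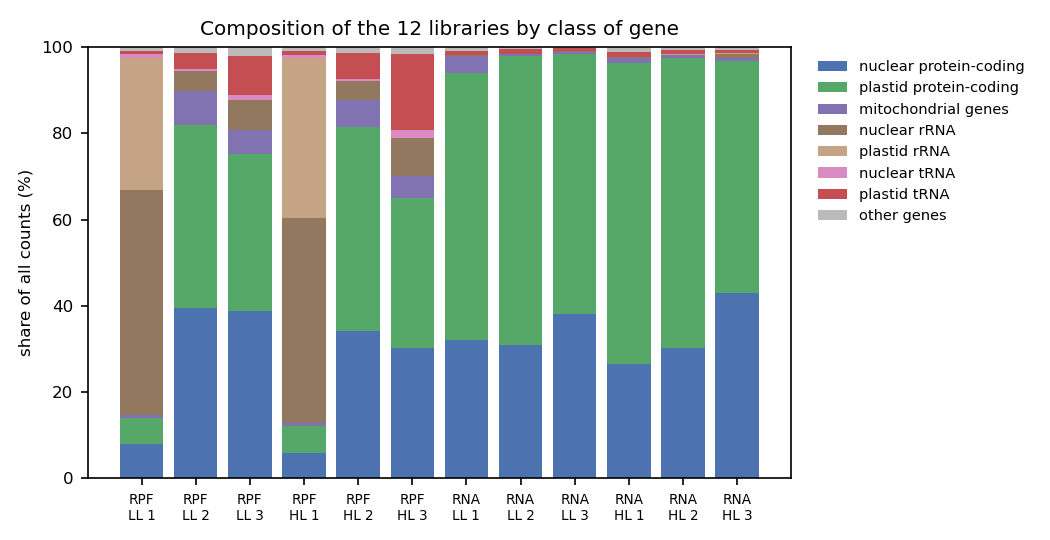
Share of all counts (%) taken by each class of gene in each of the 12 libraries, labelled by kind, light level and number. The 2 RPF libraries of number 1 consisted mostly of rRNA counts, with nuclear rRNA at 52.1% in low light and 47.5% in high light.

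The first comparison asked which transcripts gained or lost ribosome footprints within 10 min of high light. MBF1C and HSP101, of the heat-shock list, and DREB2A, of the early stress transcription factors, were among the largest rises in RPF. MBF1C (AT3G24500, TAIR10 chromosome 3, 8918679 to 8919683), a transcriptional coactivator of heat responses, rose from 3.57 ± 2.60 to 78.5 ± 25.6 CPM (SD, n = 3), a log2 change of 4.29 ± 0.42 (SE, adjusted p = 0.000774). DREB2A (AT5G05410, chromosome 5, 1602205 to 1603926), a drought and heat transcription factor, rose from 6.96 ± 2.84 to 77.8 ± 15.1 CPM (SD, n = 3), by 3.53 ± 0.32 (SE, adjusted p = 0.000774). HSP101 (AT1G74310, chromosome 1, 27936508 to 27940190), a disaggregating chaperone, rose by 3.00 ± 0.53 (SE, adjusted p = 0.0386). PDX1.2, a pseudoenzyme of vitamin B6 synthesis, rose by 3.33 ± 0.36, and the heat-shock factor AT-HSFB2B by 3.18 ± 0.46. The rises of AT1G71000, AT1G54050 and AT2G20560, which the reference table gives no symbol, were 4.27 ± 0.45, 4.00 ± 0.40 and 3.78 ± 0.42. AT1G59860 had 2 counts in low light and 154 in high light, a ratio of 87.8 (95% counting interval 23.9 to 732). AT1G66080 had 2 and 65 counts, a ratio of 37.1 (9.86 to 313).

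edgeR called 24 of 10759 genes in RPF, 24 higher and 0 lower, and 360 had an unadjusted p under 0.05. Evenly spread p-values would give 538. In the simulations of this fit, with pairing by number built in, only 0.485% of unchanged genes had a p under 0.05. If these libraries are paired likewise, 538 is not the number expected by chance. DESeq2 called 36 higher and 2 lower, and limma-voom 22 higher and 0 lower. With the replicate number as a block 150 genes were higher and 46 lower, and all 24 were among those higher. DESeq2 with the block called 53 higher and 6 lower, and limma-voom with the block 160 and 51. With the block and without the number 1 libraries 48 were higher and 7 lower. The count of 24 moved to 15 without LL 1, 7 without LL 2, 14 without HL 2, 7 without LL 3 and 7 without HL 3, and to 5 when rRNA, tRNA and all other genes were included in the fit. HSP101 missed the threshold without LL 1 (adjusted p = 0.132), LL 2 (0.104), HL 2 (0.25), LL 3 (0.0743) and HL 3 (0.542). AT1G66080 missed it without LL 1 (0.0536), LL 2 (0.108), LL 3 (0.134) and HL 3 (0.211), AT-HSFB2B without LL 2 (0.0911), HL 2 (0.123), LL 3 (0.158) and HL 3 (0.175), and AT2G20560 without LL 3 (0.053). HSP101 also missed it with DESeq2 (0.114), with a stricter filter (0.051), with all genes in the fit (0.409) and without both number 1 libraries (0.122), and AT-HSFB2B with limma-voom (0.0955) and with all genes in the fit (0.103).

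**Figure D2:**
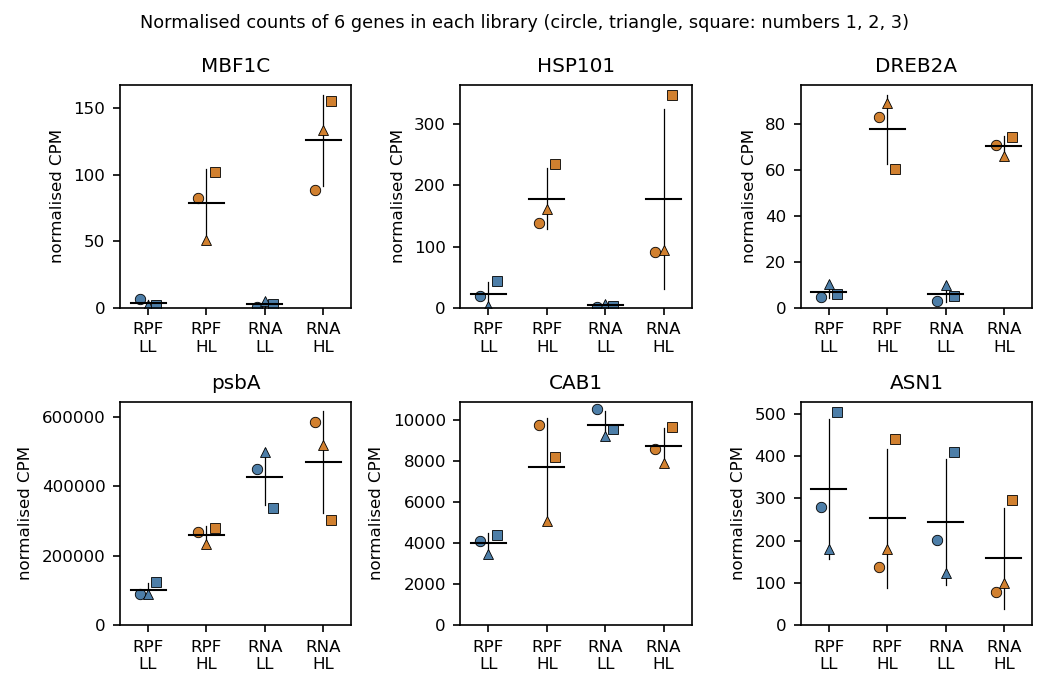
Normalised CPM of 6 genes in each library; symbols mark numbers 1 to 3, bars the mean and thin lines the SD of 3 libraries. MBF1C, HSP101 and DREB2A were higher in all high-light libraries in both kinds, psbA in RPF was higher in all high-light libraries, and its total RNA values overlapped.

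Of the fixed gene lists, heat shock and protein folding moved most in RPF, with a median log2 change of 2.56 over 10 measured members. Of these 5 rose and 0 fell, and 8 rose when adjusted over the list alone. HSP70 (AT3G12580) rose from 63.5 to 436 CPM, by 2.77 ± 0.38 (SE, n = 3, adjusted p = 0.00691), and HSP90.1 by 2.63 ± 0.40 (adjusted p = 0.0121). The list stood above other genes by camera (adjusted p = 2.84e-22; adjusted p = 0.0595 with an estimated correlation) and moved one way by fry (adjusted p = 0.0388). With the block 8 of the 10 rose. The HSP70 call was lost without LL 2 (adjusted p = 0.108), HL 2 (0.0514) and HL 3 (0.152), and the HSP90.1 call without LL 1 (0.0536), LL 2 (0.189), LL 3 (0.0505) and HL 3 (0.189). Both were lost with all genes in the fit (0.0915 for HSP70 and 0.142 for HSP90.1), and HSP90.1 without both number 1 libraries (0.0607).

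Genes for the light-harvesting antenna, the chlorophyll-binding proteins of both photosystems, had positive RPF changes in 19 of 19 members, with a median of 0.30. None of the 19 passed over all genes and 0 passed when adjusted over the list alone; with the block 8 rose, and 10 when adjusted over the list alone. The list stood above other genes (adjusted p = 0.000336; adjusted p = 0.862 with an estimated correlation), but not without LL 2 (0.057) or HL 3 (0.474). CAB1, the most abundant member, had a log2 change of 0.94 ± 0.29 (SE, adjusted p = 0.862), and with the block rose by 0.90 ± 0.11 (adjusted p = 9.99e-12). LHB1B1 and CAB3 had changes of 1.03 ± 0.37 and 0.92 ± 0.32 and rose with the block by 0.99 ± 0.12 and 0.87 ± 0.12. These members have near-identical copies, so their single values are uncertain. Cytosolic ribosomal proteins were positive in 33 of 36 members, with a median of 0.33 and 0 members past the threshold, also 0 when adjusted over the list alone. That list stood above other genes (adjusted p = 1.11e-05; adjusted p = 0.615 with an estimated correlation), but not without HL 1 (0.0638), and with the block 3 members rose, 14 when adjusted over the list alone. PFL and RPS18C were among them, with block changes of 0.82 ± 0.22 (adjusted p = 0.0169) and 0.69 ± 0.18 (adjusted p = 0.0163). Their changes without the block were 0.80 ± 0.30 and 0.69 ± 0.26, both with adjusted p = 1. DESeq2 with the block called neither PFL nor RPS18C, nor did the block without number 1.

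Early stress transcription factors were positive in 5 of 7 members, with a median of 0.57; DREB2A alone rose, also when adjusted over the list alone. The list stood above other genes (adjusted p = 0.000683; adjusted p = 0.615 with an estimated correlation), but not without LL 1 (0.826), HL 1 (0.201), HL 2 (0.0688) or both number 1 libraries (0.32, with the block 0.362). Its medians within pairs were 1.11, -0.54 and 0.84. MYBR1 had a change of 0.74 ± 0.30 and rose with the block by 0.80 ± 0.18 (adjusted p = 0.00118). Early genes of calcium, touch and wounding were positive in 7 of 8 members, with a median of 0.46 and 0 members past the threshold, also 0 when adjusted over the list alone. The list stood above other genes (adjusted p = 0.00298; adjusted p = 0.615 with an estimated correlation), but not without LL 1 (0.0927), HL 3 (0.102) or both number 1 libraries (0.104, with the block 0.0617). JAZ1, a repressor of jasmonate signalling, had a change of 0.99 ± 0.38 and rose with the block by 1.00 ± 0.27 (adjusted p = 0.0239). Genes of carbon starvation and sugar response stood below other genes, with a median of -0.47 and 1 of 11 members positive (adjusted p = 0.00122; adjusted p = 0.615 with an estimated correlation), but not without HL 1 (0.201) or both number 1 libraries (0.31, with the block 0.13). Its medians within pairs were -0.86, -0.54 and -0.02. No member passed over all genes or when adjusted over the list alone; with the block 3 fell, 6 when adjusted over the list alone. DIN10 was at -0.70 ± 0.35 (adjusted p = 1) and with the block fell by 0.73 ± 0.16 (adjusted p = 0.0013). DESeq2 with the block called none of MYBR1, JAZ1 and DIN10 in RPF, nor did the block without number 1.

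Plastid-encoded proteins were positive in 17 of 70 members, with a median of -0.12, below other genes with the block alone (adjusted p = 0.0525, with the block 0.012; adjusted p = 0.774 with the block and an estimated correlation). psbA (plastid genome, 383 to 1444) went against the list. It had 101000 CPM in low light and 260100 in high light, a log2 change of 1.36 ± 0.26 (SE, n = 3, adjusted p = 0.0754). It was the 1 member that passed when adjusted over the list alone, and with the block it rose by 1.38 ± 0.09 (adjusted p = 2.45e-34). DESeq2 called it higher without the block too, by 1.37 (adjusted p = 3.27e-05), while the other fits without the block did not (0.0599 to 1). rbcL, the large subunit of Rubisco, had a change of 0.43 ± 0.24 and rose with the block by 0.43 ± 0.09 (adjusted p = 0.0008). DESeq2 with the block did not call rbcL, nor did the block without number 1. With the block 2 members rose and 1 fell, 2 and 5 when adjusted over the list alone. The plastid-encoded list passed without LL 1 (adjusted p = 0.00643), HL 2 (3.6e-05) and LL 3 (0.0121).

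Without the block and with all libraries in the fit, 4 further lists of nuclear-encoded plastid proteins did not pass in RPF. Electron transport genes had a median of 0.10 with 27 of 32 positive (adjusted p = 0.117, with the block 0.0381). Calvin-Benson cycle genes had a median of 0.18 with 16 of 20 positive (adjusted p = 0.086, with the block 0.0138); with the block 2 members rose, 5 when adjusted over the list alone, and the list moved one way by fry (adjusted p = 0.0221). Plastid ribosomal proteins had a median of 0.17 with 28 of 34 positive (adjusted p = 0.0552, with the block 0.0146), and with the block 1 member rose, 2 when adjusted over the list alone. Plastid transcription, translation and chaperone genes had a median of -0.18 with 4 of 21 positive (adjusted p = 0.0558, with the block 0.024). With the block and an estimated correlation these lists had adjusted p = 0.677, 0.636, 0.636 and 0.68. NPQ4, the photosystem II protein of heat dissipation, had a change of 0.48 ± 0.25 and rose with the block by 0.49 ± 0.14 (adjusted p = 0.0301). DESeq2 with the block did not call NPQ4, nor did the block without number 1. Electron transport passed without HL 2 (0.000125) and LL 3 (5.49e-05), the Calvin-Benson cycle without LL 1 (0.0437), HL 2 (0.0127) and LL 3 (0.0185). Plastid ribosomal proteins passed without LL 1 (0.00539), HL 2 (5.07e-05) and LL 3 (0.0128), and plastid transcription, translation and chaperones without LL 1 (0.0151) and HL 2 (0.00464).

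The other lists did not stand apart in RPF with or without the block; without LL 3 the epidermis list did (adjusted p = 0.0394). Median log2 changes were -0.11 for tetrapyrrole and chlorophyll synthesis (21 members, adjusted p = 0.557), -0.03 for cytosolic translation factors and TOR (15, 0.887; mean 0.05), 0.09 for antioxidants and photoprotection (19, 0.473), and -0.14 for light signalling (10, 0.557). They were -0.15 for shade response and growth (4, 0.657), 0.14 for transcripts with conserved upstream reading frames (3, 0.513), -0.10 for the circadian clock (8, 0.363), and 0.04 for mitochondrial stress response (3, 0.941), which camera placed below other genes. For markers of guard cells, epidermis and trichomes, and phloem the medians were 0.05 (3, 0.77), 0.21 (5, 0.254) and -0.09 (4, 0.941). In these lists 0 members passed over all genes. PRR5, a clock component, passed when adjusted over the clock list alone, with a change of -0.84 ± 0.25 (adjusted p over all genes = 0.814), and fell with the block, at -0.81 ± 0.17 (adjusted p = 0.000528). DESeq2 with the block did not call PRR5 in RPF.

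The second comparison asked the same of transcript abundance, in total RNA. HSFA2, HSP101, MBF1C and FKBP65, of the heat-shock list, were among the largest rises. HSFA2 (AT2G26150, chromosome 2, 11135682 to 11137396), a heat-shock transcription factor, rose by 6.59 ± 0.71 (SE, n = 3, adjusted p = 0.00311), from 18 counts in low light, all of them in library 2, to 2411. HSP101 rose from 3.75 ± 2.80 to 178 ± 147 CPM (SD, n = 3), by 5.41 ± 0.67 (adjusted p = 0.00679). MBF1C rose from 2.85 ± 1.94 to 126 ± 33.9 CPM, by 5.26 ± 0.43 (adjusted p = 0.000481). FKBP65, a peptidyl-prolyl isomerase, and Hop3, a co-chaperone, rose by 5.23 ± 0.74 and 5.51 ± 0.74. PDX1.2 rose by 4.67 ± 0.35 and AT1G59860 by 6.79 ± 0.51 (adjusted p = 0.000266 each). The rises of AT1G71000, AT2G20560 and HSP17.8 (AT1G07400) were 5.33 ± 0.60, 4.95 ± 0.49 and 4.25 ± 0.61. The genes that fell were AT5G21940 (chromosome 5, 7249268 to 7250539), at -1.49 ± 0.23 (SE, adjusted p = 0.0269) and AT5G61590 (chromosome 5, 24764438 to 24765324), at -1.49 ± 0.22 (adjusted p = 0.0215).

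edgeR called 35 genes higher and 2 lower of 15701 in total RNA, and 371 had an unadjusted p under 0.05. Evenly spread p-values would give 785. In the simulations of this fit, with pairing by number built in, only 0.497% of unchanged genes had a p under 0.05. DESeq2 called 55 higher and 9 lower, the fit without a filter 52 and 6, and the block 85 and 45; all 37 were called with the block. DESeq2 with the block called 70 higher and 34 lower, and limma-voom with the block 86 and 56. Without LL 3 the count was 14, and without both number 1 libraries 22. AT5G21940 missed the threshold without LL 1 (adjusted p = 0.0776), LL 2 (0.0534), HL 2 (0.165), LL 3 (0.128) and HL 3 (0.2), and AT5G61590 without LL 1 (0.0776), HL 1 (0.0732), HL 2 (0.158), LL 3 (0.0987) and HL 3 (0.194). Hop3 and HSP101 missed it without LL 3 (0.128 and 0.0857), FKBP65 without LL 1 (0.0882) and LL 3 (0.135), and AT1G07400 without LL 3 (0.0918) and HL 3 (0.0571). Hop3 also missed it with limma-voom (0.147). Without both number 1 libraries FKBP65 (0.0505), AT1G07400 (0.0621), AT5G21940 (0.0895) and AT5G61590 (0.199) missed it.

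Among the lists in total RNA, heat shock and protein folding had a median log2 change of 3.94 over 12 members, all positive. Of these 6 rose, 12 when adjusted over the list alone and 10 with the block. The list stood above other genes (adjusted p = 4.29e-38; adjusted p = 0.182 with an estimated correlation). HSP70 went from 11.2 ± 13.5 to 249 ± 128 CPM (SD, n = 3), a change of 4.37 ± 0.76 (SE, adjusted p = 0.053), and rose with the block by 4.72 ± 0.50 (adjusted p = 0.000106); it also passed without a filter (adjusted p = 5.57e-05), with DESeq2 (0.0141), with limma-voom (0.0266), and without HL 1 (0.0369) or LL 2 (0.0023). Calcium, touch and wound genes were positive in 14 of 14 members, with a median of 0.38 (adjusted p = 3.75e-06; adjusted p = 0.497 with an estimated correlation), but did not pass without both number 1 libraries (0.0575). Its medians within pairs were 1.05, 0.17 and 0.39. None passed over all genes, 1 passed when adjusted over the list alone, and with the block 1 rose, 4 over the list alone. CAF1a, a deadenylase, had a change of 1.2 ± 0.31 and rose with the block by 1.16 ± 0.20 (adjusted p = 0.0118). DESeq2 with the block did not call CAF1a. Early stress transcription factors were positive in 14 of 19 members, with a median of 0.45 (adjusted p = 5.42e-05; adjusted p = 0.69 with an estimated correlation), but did not pass without LL 1 (0.058) or both number 1 libraries (0.0808, with the block 0.122). Its medians within pairs were 1.07, -0.22 and 0.66. DREB2A rose by 3.45 ± 0.34 (adjusted p = 0.00172), and adjusted over the list alone 2 rose and 1 fell. With the block 2 rose, and adjusted over the list alone 6 rose and 2 fell. MYBR1 had a change of 1.00 ± 0.27 and rose with the block by 1.01 ± 0.15 (adjusted p = 0.0031). Mitochondrial stress genes were positive in 6 of 7 members, with a median of 0.24 and 0 members past the threshold (adjusted p = 0.0372; adjusted p = 0.548 with an estimated correlation). That call was lost without LL 1 (0.114), HL 1 (0.0524), LL 3 (0.0648), HL 3 (0.177) and both number 1 libraries (0.0826, with the block 0.0774).

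Carbon starvation and sugar genes stood below other genes in total RNA, with a median of -0.63 and 2 of 11 members positive (adjusted p = 5.06e-05; adjusted p = 0.548 with an estimated correlation). No member passed over all genes or when adjusted over the list alone; with the block 3 fell, 8 when adjusted over the list alone. ERD5, a proline dehydrogenase, was at -1.01 ± 0.38 and with the block fell by 1.06 ± 0.18 (adjusted p = 0.00769). TPS9 was at -0.77 ± 0.31 and fell with the block, at -0.77 ± 0.16 (adjusted p = 0.0347). DESeq2 with the block did not call TPS9, nor did the block without number 1. In 3 further lists, all below other genes, 0 members passed over all genes or when adjusted over the list alone. Plastid transcription, translation and chaperone genes had a median of -0.23 with 4 of 21 positive (adjusted p = 0.0112; adjusted p = 0.69 with an estimated correlation). The call of that list was lost without LL 1 (0.0563), LL 3 (0.515) and both number 1 libraries (0.0768). Antenna genes had a median of -0.20 with 1 of 20 positive (adjusted p = 0.0355; adjusted p = 0.748 with an estimated correlation). Tetrapyrrole and chlorophyll synthesis genes had a median of -0.18 with 2 of 21 positive (adjusted p = 0.0372; adjusted p = 0.748 with an estimated correlation). The antenna and tetrapyrrole calls were lost without HL 1 (0.638 and 0.295), HL 2 (0.0792 and 0.174) and both number 1 libraries (0.0826 and 0.0982), and without LL 3 the direction turned (0.954 for both). CAB1 had a total RNA change of -0.16 ± 0.34 (adjusted p = 1).

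Cytosolic ribosomal proteins in total RNA had a median of 0.14 with 30 of 37 positive (adjusted p = 0.148, with the block 0.0129; adjusted p = 0.73 with the block and an estimated correlation), and passed without LL 2 (0.00131) and HL 3 (0.000313). Plastid-encoded proteins had a median of 0.05 with 46 of 77 positive (adjusted p = 0.239), and psbA a change of 0.14 ± 0.57 (SE, n = 3, adjusted p = 1). The plastid-encoded list passed without HL 3 (7.16e-07), and without both number 1 libraries it turned below other genes (7.05e-08, with the block 2.97e-06). The remaining lists did not stand apart, and 0 of their members passed over all genes. Their medians were -0.05 for electron transport (32 members, adjusted p = 0.188), -0.08 for the Calvin-Benson cycle (20, 0.294), -0.07 for plastid ribosomal proteins (34, 0.163), and -0.15 for cytosolic translation factors and TOR (15, 0.239). They were -0.05 for antioxidants and photoprotection (19, 0.239), -0.17 for light signalling (12, 0.294), -0.24 for shade response (7, 0.339), and -0.16 for transcripts with upstream reading frames (3, 0.545). For the circadian clock the median was -0.10 (11, 0.362), and for markers of guard cells, epidermis and phloem -0.25 (4, 0.44), 0.01 (5, 0.362) and -0.22 (4, 0.44). Flavonoid synthesis and the markers of meristems and dividing cells had medians of -0.04 (3, 0.541) and -0.14 (5, 0.516), while camera placed both above other genes. The clock had a mean of 0.02 and the epidermis list a mean of -0.15, opposite in sign to their medians. Without LL 2 electron transport (adjusted p = 0.00769), the Calvin-Benson cycle (0.0226), plastid ribosomal proteins (0.0065) and antioxidants (0.0471) passed, and without HL 2 electron transport and plastid ribosomal proteins (0.0303 each). Flavonoid synthesis passed without HL 1 (0.0252), and meristem markers turned below other genes without LL 1 (0.0377) and without both number 1 libraries (0.0431). PRR5 passed when adjusted over the clock list alone, at -0.87 ± 0.23 (adjusted p over all genes = 0.537), and fell with the block, at -0.85 ± 0.16 (adjusted p = 0.0186).

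**Figure D3:**
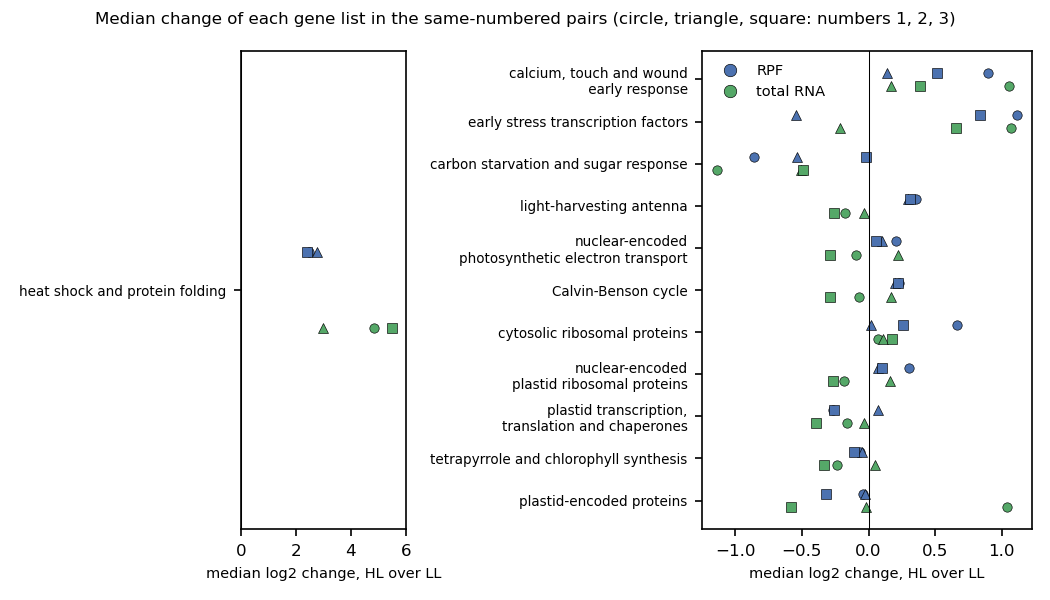
Median log2 change, high over low light, of 12 gene lists in each same-numbered pair of libraries, in RPF and in total RNA; the heat-shock list has its own axis. Heat-shock medians lay between 2.4 and 2.76 in RPF and between 2.98 and 5.49 in total RNA, and antenna medians were positive in RPF and negative in total RNA in all 3 pairs.

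RPF and total RNA changes were set against each other across the 10727 genes tested in both. The 20 genes higher in both, MBF1C, HSP101, DREB2A and PDX1.2 among them, were taken from 24 in RPF and 33 in total RNA, where lists drawn independently would share 0.0738. That figure assumes independence, which these libraries lack: same-numbered RPF and total RNA libraries correlated at 0.13 to 0.27 after group means were removed. The overlap was 13 genes without number 1, and 0 without number 2 and 0 without number 3. In those last fits edgeR called 0 of these genes in RPF, with 443 and 210 at an unadjusted p under 0.05, and 19 and 4 higher in total RNA. With the block 56 genes were higher in both and 24 lower in both, against 1.03 and 0.184 for lists drawn independently, and 0 were called in opposite directions. Pearson's r of the log2 changes was 0.50 and Spearman's rho 0.28 across genes, which are not independent replicates. For the 1999 genes with a mean log2 CPM of at least 5 in both kinds r was 0.75.

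**Figure D4:**
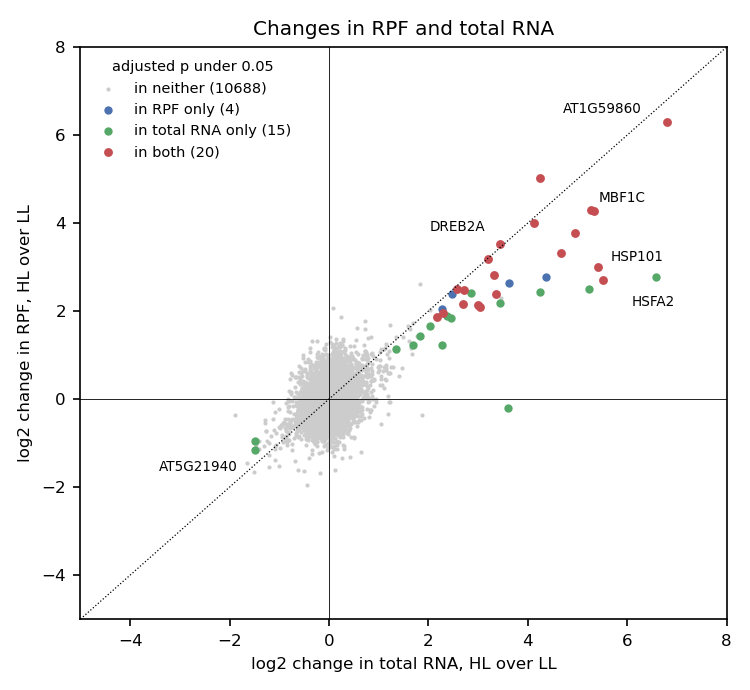
Log2 change in RPF against log2 change in total RNA, high over low light, for the 10727 genes tested in both, coloured by which test each gene passed; the dotted line marks equal changes. Of the genes shown, 20 passed in both, 4 in RPF alone and 15 in total RNA alone.

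The third comparison asked which transcripts changed in translational efficiency, that is in RPF relative to total RNA. No single gene passed, and the genes with the smallest p are given as values alone. CBL10, a calcium sensor, was at -1.62 ± 0.44 (SE, n = 3 per group), HSFA2 at -3.80 ± 1.08, AT5G47970 at -1.86 ± 0.52, AT3G54130 at -2.33 ± 0.65 and AT5G11910 at -2.13 ± 0.64, each with adjusted p = 1. psbA was at 1.22 ± 0.58 (adjusted p = 1). edgeR called 0 of 12789 genes, and 179 had an unadjusted p under 0.05. Evenly spread p-values would give 639. In the simulations of this fit, with pairing by number built in, only 0.655% of unchanged genes had a p under 0.05. DESeq2 called 0, limma-voom 0 and the block 0, while the fit without a filter called 2 lower, HSFA2 (adjusted p = 0.00682) and HSFA7A (0.0213), and DESeq2 with the block 1 higher, LHB1B1. The block gave RPF and total RNA 1 shared effect per number, so differences between numbers particular to 1 kind stayed in its error. In the simulations 1.44% of unchanged genes had a p under 0.05 with it. A block for each light level and number also called 0.

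In the heat-shock list 10 of 10 members had negative changes of translational efficiency, with a median of -1.72. Within same-numbered pairs the medians were -2.67, -0.24 and -3.29, with 8, 6 and 10 of 10 members negative, so pair 2 showed little of the difference. The list stood below other genes by camera (adjusted p = 1.02e-06; adjusted p = 0.676 with an estimated correlation) but did not move one way by fry (adjusted p = 0.96). None passed over all genes and 4 fell when adjusted over the list alone. HSFA7A was at -3.79 ± 1.13 (SE), FKBP65 at -2.73 ± 0.98 and HSP70 at -1.61 ± 0.88, each with adjusted p = 1. The ratio of RPF to total RNA of this list, as the log2 median of its members, was 2.03 ± 1.54 in low light and 0.71 ± 0.17 in high light (SD, n = 3), against 0.51 ± 0.10 and 0.58 ± 0.04 for all protein-coding genes. These ratios covered at least 17 members in low light and 18 in high light, not the 10 above, with 1 count added to each value. Where total RNA counts were near 0 the added count sets the ratio, as for HSFA2 with 0 counts in low-light libraries 1 and 3.

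Antenna genes had positive changes of translational efficiency in 20 of 20 members, with a median of 0.42. The list stood above other genes by camera (adjusted p = 4.24e-06; adjusted p = 0.924 with an estimated correlation), but not without RPF HL 3 (0.0824), and did not move one way by fry (adjusted p = 0.96). None passed over all genes or when adjusted over the list alone; with the block 3 rose when adjusted over the list alone. CAB3 was at 1.13 ± 0.46 (SE), CAB1 at 1.09 ± 0.44 and LHB1B1 at 1.25 ± 0.57, each with adjusted p = 1; DESeq2 with the block called LHB1B1 higher, at 1.26 (adjusted p = 0.000139), while the other fits gave 0.764 to 1. The antenna ratio of RPF to total RNA was -0.20 ± 0.02 in low light and 0.27 ± 0.26 in high light (log2, SD, n = 3). Plastid ribosomal proteins were positive in 33 of 34 members, with a median of 0.22 (adjusted p = 0.00592). Calvin-Benson cycle genes were positive in 17 of 20, with a median of 0.30 (adjusted p = 0.0176), and electron transport genes in 30 of 32, with a median of 0.17 (adjusted p = 0.0193). Plastid-encoded proteins stood below other genes, with a median of -0.19 and 20 of 75 positive (adjusted p = 0.00985), and their ratio was 1.15 ± 0.55 in low light and 0.84 ± 0.41 in high light (log2, SD, n = 3). In these 4 lists 0 members passed over all genes or when adjusted over the list alone, and each had adjusted p = 0.924 with an estimated correlation.

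The calls of those 4 lists were lost when single libraries were left out. For plastid ribosomal proteins these were total RNA LL 1 (adjusted p = 0.125), RPF HL 1 (0.707), RPF LL 2 (0.707), RPF HL 3 (0.0729) and total RNA HL 3 (0.112). For the Calvin-Benson cycle they were total RNA LL 1 (0.125), RPF HL 1 (0.181), RPF LL 2 (0.54), total RNA LL 3 (0.213) and RPF HL 3 (0.21). For electron transport they were RPF LL 1 (0.104), RPF HL 1 (0.181), total RNA HL 1 (0.238), RPF LL 2 (0.886), total RNA LL 3 (0.667) and RPF HL 3 (0.744). For plastid-encoded proteins they were total RNA LL 1 (0.614), RPF HL 1 (0.0724), total RNA HL 1 (0.991), RPF LL 2 (0.414), total RNA HL 2 (0.0678) and RPF HL 3 (0.59). Without both LL 2 libraries the 4 lists, in this order, had 0.156, 0.0785, 0.323 and 0.0669, and without both HL 1 libraries 0.534, 0.29, 0.534 and 0.97. Without both LL 1 libraries the calls of the last 3 were lost (0.113, 0.113 and 0.773), and without both HL 3 libraries those of the first 3 (0.394, 0.317 and 0.803). Without all number 1 libraries plastid ribosomal proteins (0.583, with the block 0.534), the Calvin-Benson cycle (0.355, 0.254) and electron transport (0.698, 0.575) did not pass, and the direction of the plastid-encoded list turned (0.355, with the block 0.534).

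The other lists did not stand apart in translational efficiency, and in them 0 members passed over all genes or when adjusted over the list alone. Medians were 0.23 for cytosolic ribosomal proteins (37 members, adjusted p = 0.0541), 0.16 for tetrapyrrole synthesis (21, 0.477), 0.08 for plastid transcription, translation and chaperones (21, 0.789), and 0.15 for cytosolic translation factors and TOR (15, 0.507). They were -0.07 for early stress transcription factors (14, 0.789), -0.06 for calcium, touch and wound genes (9, 0.832; mean 0.18), 0.13 for antioxidants (19, 0.176), and 0.13 for light signalling (10, 0.789). For shade response the median was -0.05 (5, 0.884; mean 0.01), for carbon starvation 0.24 (11, 0.607), for upstream reading frames 0.41 (3, 0.511), and for the clock 0.01 (9, 0.884; mean -0.07). Mitochondrial stress genes were at -0.17 (5, 0.72), and markers of guard cells, epidermis and phloem at 0.23 (3, 0.832), 0.16 (5, 0.207) and 0.12 (4, 0.789). Cytosolic ribosomal proteins passed without RPF HL 2 (0.00195), total RNA HL 2 (1.56e-05), RPF LL 3 (0.0387) and total RNA LL 3 (0.000117), and early stress transcription factors without RPF LL 1 (0.0208) and total RNA LL 2 (0.0317). Without total RNA LL 2 or RPF LL 3 tetrapyrrole synthesis (0.0121 and 0.0387), antioxidants (0.0291 and 0.034) and epidermis markers (0.0418 and 0.0387) passed, and carbon starvation without total RNA HL 3 (0.0324). Without both LL 3 libraries cytosolic ribosomal proteins (0.00011) and epidermis markers (0.0341) passed, and without both HL 2 libraries cytosolic ribosomal proteins (1.17e-07).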

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

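All tests of explanations in this part, and the splits of the samples, were chosen after the results were seen; the gene lists and the interaction test were fixed before the data were examined. The test of the number 1 libraries for the antenna was restated after a first form, which asked for opposite signs alone and found them in 2 of 2 pairs, had been seen. The test of low counts for heat shock was restated likewise, since its first form, 5 members with at least 50 low-light counts over 3 libraries (median -1.61, SD 1.06, 5 of 5 negative), let library 2 supply most of the counts of members such as HSP101.

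The interaction test gave 6 lists that differed between RPF and total RNA at the preset correlation and 0 with an estimated one. Median changes were -1.72 for heat shock, 0.42 for the antenna, 0.22 for plastid ribosomal proteins, 0.30 for the Calvin-Benson cycle, 0.17 for electron transport and -0.19 for plastid-encoded proteins. Of these, heat shock and the antenna are weighed below.

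Heat-shock genes had smaller changes in RPF than in total RNA, with a median translational efficiency change of -1.72 in 10 members (adjusted p = 0.676 with an estimated correlation), but pair 2 showed little of this, with medians within pairs of -2.67, -0.24 and -3.29 and 8, 6 and 10 of 10 members negative. High-light fragments carried into all low-light RPF libraries at a common share are argued against. AT1G59860, AT1G66080 and MBF1C together gave a pooled ratio of 3.91%, with an upper 95% limit of 5.83% for counting error. The median excess of the list was 11.7%, and 8 of 10 members lay above the limit. The 3 genes behind the limit had the largest rises in RPF, which favours a low limit, and MBF1C is itself in the list. A share that differed between libraries was not tested. Too few low-light counts stay undecided, since members with at least 20 in both low-light libraries of a pair had a median of 0.24 in pair 2 (3 members, SD 0.41) and -3.29 in pair 3 (4 members, SD 1.87), with 0 such members in pair 1. Whether induced transcripts in general gain less RPF than total RNA stays undecided: genes called in RPF outside the list had a median of -0.36 (SE 0.217, 16 of 19 negative), but 4 of them, HSP81-2, AT-HSFB2B, Fes1A and Hop3, have names of the same class. Genes without a symbol, AT1G59860, AT1G54050, AT2G20560 and AT1G71000 among them, could not be classed by name, so more may belong to it. A candidate biological explanation, newly made transcripts not yet on ribosomes after 10 min, was not tested. In high light the log2 ratio of RPF to total RNA of the heat-shock list was 0.71 ± 0.17, against 0.58 ± 0.04 for all protein-coding genes (SD, n = 3). The list was therefore not below other genes there, while its low-light ratio was 2.03 ± 1.54.

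psbA rose in RPF with the block and, without it, with DESeq2 (1.37, adjusted p = 3.27e-05) but not with edgeR (1.36, adjusted p = 0.0754) or in the other fits without the block (0.0599 to 1), while its total RNA change was not resolved. A joint rise of all plastid footprints is argued against by the other 69 plastid genes, with a median of -0.14 (SD 0.172; highest rbcL at 0.43), and the rRNA-rich number 1 libraries by a change of 1.29 (SE 0.159, adjusted p = 7.42e-05) without them and with the block. The test of a rise of psbA RNA that total RNA could not resolve was undecided. The 95% interval of the total RNA change reached 1.25 with the block (from -1.05) and 1.4 without it (from -1.13), against an RPF change of 1.38. A first form of this interval, with 2 residual degrees of freedom in place of 13.6 total ones, reached 2.39 and was replaced after its value was seen. In pairs 1, 2 and 3 psbA went from 448577 to 584895, 497574 to 520181 and 336947 to 303843 CPM in total RNA. In RPF it went from 90350 to 267887, 88458 to 233202 and 124083 to 279299 CPM. The values of the single libraries argue against a rise of psbA RNA as the whole source of the RPF rise. Whether a smaller rise of its RNA had a part may not be read from these values.

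Antenna genes were positive in RPF in 19 of 19 members and negative in total RNA in 19 of 20, with a median translational efficiency change of 0.42 in 20 members (adjusted p = 0.924 with an estimated correlation, and 0.0824 at the preset one without RPF HL 3). Reads shared between near-identical copies are argued against as the whole cause, since the 10 members that are the single gene of their type had a median of 0.37 (SE over members 0.119, 10 of 10 positive), against 0.60 in members with copies. Because members varied together, neither this SE nor the count of positive members measures the spread over libraries. For a shift of abundant transcripts as a whole, other genes of like abundance shifted less in the form used. There the antenna median lay at percentile 100 of 10000 matched lists (median 0.087, middle 95% up to 0.234), but a first form gave percentile 92.2 (median 0.25, up to 0.697). Matched genes were drawn 1 by 1, while antenna members varied together (estimated correlation 0.617). The matched lists thus spread too little for the percentile to decide. In that first form, which also let list members be drawn, ranks past the end fell on psbA (25.8% of draws, change 1.22), and with that alone mended the percentile was 100; since it was replaced after its value was seen, this evidence is weaker than a test fixed beforehand. The rRNA-rich number 1 libraries are argued against as the source of the difference, which was at least 0.34 (SD 0.128 over pairs) in the other 2 pairs, but whether total RNA fell stays undecided, since its median was -0.04 in 1 of them (SD 0.113 over pairs) and its direction turned without LL 3 (0.954).

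Plastid tRNA genes, which the main gene tests left out, held a larger share of RPF counts in high light in all 3 same-numbered pairs. The share was 0.69%, 3.72% and 9.12% in low light and 0.955%, 6.09% and 17.7% in high light, with ratios of 1.38, 1.64 and 1.94 and a median ratio of 1.64. The exact permutation test of the group means, 4.51% and 8.26%, gave p = 0.6. That test did not use the pairs, and low-light shares ranged from 0.69% to 9.12% over numbers, so it cannot weigh the rise within pairs. No explanation of this share was tested.

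The 6 samples of each kind can be split 3 against 3 in 10 ways, too few for a share under 0.05. In RPF 1 of 10 splits gave as many called genes as the real one (24, highest other 0), in total RNA 1 of 10 (37, highest other 0), and in translational efficiency, with 0 calls, 10 of 10 (highest other 0). Splits that kept 2 pairs together had up to 1351, 1953 and 988 genes with an unadjusted p under 0.05, against 360, 371 and 179 in the real split, which points to a structure by number. Among the other splits that parted all 3 pairs, the fit with the block called 0, 1 and 0 genes in RPF against 196, and 0, 0 and 0 in total RNA against 130.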

How the results depend on the processing

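Limma-voom and DESeq2 with the block, and leaving out both number 1 libraries or psbA, were chosen after seeing the data; the other alternatives were planned. Except where a construction is named, the cause was not tested.

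Numbers of called genes depended on the fit. Against 24 genes in RPF there were 46 without a filter, 38 with DESeq2, 5 with all genes in the fit, 196 with the replicate block, 211 and 59 with the block in limma-voom and DESeq2, and 55 with the block and without number 1. Against 37 in total RNA the numbers were 58 without a filter, 64 with DESeq2, 130 with the replicate block, 142 and 104 with the block in limma-voom and DESeq2, and 125 with the block and without number 1. In translational efficiency edgeR called 0 genes, with 179 at an unadjusted p under 0.05; without a filter there were 2 and with the block in DESeq2 1, while limma-voom and DESeq2 called 0. When single libraries were left out, which leaves fewer samples, RPF calls ranged from 7 (LL 2) to 21 (HL 1) and total RNA calls from 14 (LL 3) to 38 (HL 1), and translational efficiency stayed at 0. With both libraries of a number left out, edgeR called 17, 0 and 0 genes higher in RPF without numbers 1, 2 and 3, with 237, 443 and 210 at an unadjusted p under 0.05, and 20, 19 and 4 higher in total RNA, among genes tested in both; 13, 0 and 0 were shared.

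Of the list tests, 6 passed in RPF, 11 with the block and 0 with an estimated correlation. In total RNA 8 passed and 0 with an estimated correlation; in translational efficiency 6, 2 with the block and without number 1, and 0 with an estimated correlation. When libraries were left out the numbers ranged from 3 (HL 1) to 11 (LL 3) in RPF, from 4 (LL 3) to 13 (LL 2) in total RNA, and from 1 (RPF HL 3) to 10 (RNA LL 2) in translational efficiency.

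Some list directions turned. With the block and without number 1 these were meristem markers (adjusted p = 0.0383) and plastid-encoded proteins (2.97e-06) in total RNA, and plastid-encoded proteins in translational efficiency (0.534). Over left-out libraries the adjusted p in total RNA ranged from 5.03e-05 (HL 3) to 0.954 (LL 3) for the antenna, from 0.000506 (LL 2) to 0.954 (LL 3) for tetrapyrrole synthesis, from 0.0377 (LL 1) to 0.763 (HL 3) for meristem markers, and from 7.05e-08 (number 1) to 0.652 (HL 2) for plastid-encoded proteins. Plastid-encoded proteins in translational efficiency ranged from 1.41e-09 (RNA HL 3) to 0.991 (RNA HL 1).

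The correlation of RPF and total RNA changes was 0.50, 0.75 for genes with a mean log2 CPM of at least 5, and 0.38 (without number 3) to 0.42 (without number 1) when numbers were left out. The high-minus-low difference of the plastid share in RPF, 6.78 percentage points, was 1.22 with all genes in the denominator and -0.66 without the most counted gene; that of the nuclear share was then 0.66.

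Of 268 results for named genes, leaving out libraries gave 2758 values that stayed, 43 with a lost call, 2 with a gained call and 95 that moved. The other alternatives gave 3212, 8, 70 and 18. A value stayed if it kept its call and direction. Where neither fit called the gene, it stayed if its change lay within 1 SE of the main one, whatever its sign. For 68 list tests these were 625 values with the same call, 69 lost, 40 gained and 6 turned, and 297, 28, 8 and 3 under the other alternatives. Most of the named-gene results and list tests had no call in the main fit and so could not lose one. The counts therefore do not give the share of calls that held. Of values of the 50 ratios, 150 stayed within 1 SD when libraries were left out, and 68 stayed and 19 moved otherwise. The block changed no list call by camera or by the one-way test of fry besides those given in the report. RPF libraries held 1162389 to 2119227 protein-coding counts, and 10759 genes passed the count filter in RPF against 15701 in total RNA; in simulations at a log2 change of 2 the share of changed genes called was 72.0% in RPF and 70.1% in total RNA.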

Other observations

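The genes in this part were chosen after their values were seen, from the largest changes in the fit with the block, which was planned; no explanation was tested for them.

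BT2, a scaffold protein with a BTB domain that responds to sugar and nitrogen, had 142 CPM in RPF in low light and 44.2 in high light, and with the block it fell by 1.55 ± 0.19 (SE, n = 3, adjusted p = 3.97e-12). In total RNA with the block it fell by 1.33 ± 0.21 (adjusted p = 0.00536; 0.993 without the block). AT2G20670 fell with the block, at -1.47 ± 0.21 in RPF (adjusted p = 1.62e-08) and -1.63 ± 0.19 in total RNA (adjusted p = 0.000366; 0.537 without the block). AT1G80440 fell in RPF, at -1.65 ± 0.20 (adjusted p = 4.71e-12). The zinc finger gene ATCTH and the transcription factor RAV2 fell in RPF, at -1.2 ± 0.18 (adjusted p = 2.27e-08) and -1.05 ± 0.23 (adjusted p = 0.0008), as did BCA6, a beta carbonic anhydrase, at -1.94 ± 0.39 (adjusted p = 0.000254). Without the block none of these 6 genes passed in RPF, with adjusted p from edgeR of 1, 0.0754, 0.342, 0.493, 0.78 and 0.205 in the order named. DESeq2 with the block called 6 genes lower in RPF, against 46 by edgeR.

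In total RNA, PAR1, a shade-induced growth repressor, fell with the block, at -1.33 ± 0.21 (SE, n = 3, adjusted p = 0.00593), and the thioredoxin ACHT5, at -1.59 ± 0.30 (adjusted p = 0.0193). Without the block these had adjusted p = 0.232 and 1. HSFA2, which without the block missed the threshold in RPF (2.77 ± 0.59, adjusted p = 0.125), rose there with the block by 2.91 ± 0.23 (adjusted p = 5.04e-25). Low-light total RNA library 2 held 18 counts of HSFA2 and 69 of HSP101, against 0 and 4 in library 1 and 0 and 22 in library 3.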
